A study of Homo sapiens with 6 samples.

How the data were processed

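ChIP-seq with a p63 antibody (Santa Cruz H129, per the labels) was done on formaldehyde-crosslinked, sonicated chromatin of MCFDCIS and MDA-MB-231 cells, and libraries were also made from input DNA. Samples were grouped by the cell line and antibody in the labels, which gave 2 p63 and 2 input libraries for MCFDCIS and 1 of each for MDA-MB-231. The deposited peak lists of the 3 p63 libraries were used. The inputs were not analysed here. Per the submitters' processing notes, the tools included Bowtie2 2.2.3, Picard, MACS2 2.0.10.20131216 and HOMER, and the genome build was hg19. The role of each tool, the peak threshold, the control library and the handling of duplicate reads are not given in the sources used here.

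Each list belongs to 1 library, with no pooling of replicates, as the deposited layout of 1 list per library shows. The deposited lists have the narrowPeak layout without headers. The authors' fold is a linear ratio of the pileup at the summit to the local background. The deposited −log10 p and −log10 q give the significance of each peak, and the lowest −log10 q in the lists, 1.30 to 1.32, matches a q of 0.05. The deposited score is the whole-number part of a multiple of the −log10 q and was not used. Deposited starts, ends and summit offsets were turned into positions counted from 1. A fold or q was used to rank or filter peaks within its list. Folds of different lists are given side by side, as a mean ± SD over the MCFDCIS replicates or as Spearman's rho across their shared regions, and other comparisons of height between lists use relative height, defined below.

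Depth was read from the lists. In MACS2 the fold is the summit pileup plus 1 over the local background plus 1, and the p is the Poisson upper tail of the pileup given that background. Solving both for each peak returned a whole number of fragments in 100% of the peaks of each list, with a tolerance of 0.001 in −log10 p, so the pileups were not rescaled. The solver was tested on simulated data and recovered 99.7% of 4989 simulated peaks. The lowest background in each list, 1.07, 1.34 and 1.33 fragments in replicate 1, replicate 2 and MDA-MB-231, was taken as the genome-wide background. Divided by the shortest peak width, 164, 160 and 174 bp, taken as the fragment length, it gave the relative ChIP depth, on the assumption that the same genome size was used for the 3 lists. Relative height is the pileup over the genome-wide background, and relative local background is defined likewise. The lowest summit pileup was 6, 7 and 8 fragments and the lowest −log10 p was 3.73, 4.01 and 4.84, so that the shortest list had the strictest threshold. No summit held more than 2 fragments per bp of fragment length, with a highest pileup of 327 against 328 in replicate 1, 277 against 320 in replicate 2 and 333 against 348 in MDA-MB-231. A limit of 1 read per position and strand would set this ceiling, so heights near it can be compressed.

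Peaks were called shared when they overlapped by at least 1 bp. Overlaps were set beside 100 shuffles of peak positions within chromosomes and 100 draws that moved each peak by 10 to 100 kb. Overlapping peaks of both MCFDCIS lists were merged, and a region took its values from its highest peak of each list. Shares have 95% Wilson or exact binomial intervals, pileups exact Poisson intervals, and correlations and ratios bootstrap intervals over regions (200 draws for Spearman's rho and 1000 for the ratio). Intervals cover counting error only, not the spread between cultures. The local background that MDA-MB-231 would have at an unlisted region was assumed to stand as far above its genome-wide level as in the MCFDCIS replicate it was compared with. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

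The comparisons, the overlap rule, the stricter q thresholds, the equal list lengths and the naming rule were fixed before the data were examined. The rule names the 15 shared MCFDCIS regions with the highest lower-of-2 fold, the 10 MDA-MB-231 peaks with the highest −log10 q and up to 10 MDA-MB-231 peaks in shared regions, which turned out to be those same 10. Depth, relative height, local background and the comparisons that use them were chosen after the data were seen. So were the common p threshold, the exclusion of peaks on at least 5 times the genome-wide background and the 10-fold line between weak and strong shared regions.

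No genome or gene annotation of hg19 was used here, and the gene table at hand has another build, GRCh38.p14. Positions were not converted between builds. Regions are therefore named by position alone, and planned analyses of 12 sequence motifs (the p53/p63 site among them), of peaks by genomic feature and of 18 gene lists were not run. The genes that were to be named in any case, TP63, CDKN1A, MDM2, KRT5, KRT14, ITGB4 and ZNF750, were not placed among the peaks. A relation between regions and genes per chromosome was computed and left out, since its gene numbers came from the other build.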

Results

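Binding of p63, a p53-family transcription factor that marks basal epithelial cells, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in a pair of human breast cancer cell lines. MCFDCIS is a basal-subtype line that expresses p63, and its binding regions were the subject of the study. MDA-MB-231, a breast cancer line with mesenchymal features, was the other line. The 6 libraries comprised 2 p63 libraries and 2 inputs from MCFDCIS and 1 p63 library and 1 input from MDA-MB-231. Replicate 1 of MCFDCIS and the MDA-MB-231 library carried the same date, day 20 of the month, and replicate 2 carried day 25. Peak lists of the 3 p63 libraries were analysed, and the inputs were not analysed here. The labels do not say whether the MCFDCIS replicates came from separate cultures, so the spread between them may be technical. The ChIP depth of each library, read from the background that its peaks were called against, was 1.28 times that of replicate 1 in replicate 2 and 1.17 times that of replicate 1 in MDA-MB-231.

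The first comparison asked how many p63 regions each line held. MCFDCIS held far more called p63 peaks than MDA-MB-231, which held 244. Replicate 1 listed 28239 peaks and replicate 2 listed 15238, a mean of 21738.5 ± 9193 (SD, n = 2). Within the shared date, replicate 1 listed 115.7 times as many peaks as MDA-MB-231. Replicate 2, which carried the other date, listed 62.5 times as many as MDA-MB-231. These ratios were far larger than the 1.85-fold difference between the MCFDCIS replicates. The MDA-MB-231 library was not the shallowest of the 3, since its depth was 1.17 times that of replicate 1 and 0.912 times that of replicate 2.

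Strong peaks set the lines apart further. Peaks with a fold enrichment of at least 10, as the authors' peak caller gave it, numbered 10486 in replicate 1, which was 37.1% of its list (95% Wilson interval 36.6 to 37.7). In replicate 2 there were 5591, or 36.7% (35.9 to 37.5), and in MDA-MB-231 there were 15, or 6.15% (3.76 to 9.89). A fold of at least 20 was reached by 4231, 1609 and 2 peaks. The median fold within each list was 7.54 in replicate 1, 7.74 in replicate 2 and 5.00 in MDA-MB-231, and the highest was 100.2, 70.8 and 23.1. The number of fragments over the summit had a median of 29, 34 and 16. The regions together covered 8450327 bp in replicate 1, 4147760 bp in replicate 2 and 65694 bp in MDA-MB-231. With 1 MDA-MB-231 library, the difference between the lines has no replicate check on that side and no p-value is given. At a −log10 q of at least 5 in all lists the ratios to MDA-MB-231 rose to 271.9 and 154.0, and at 10 to 395.5 and 232.2. An equal q is not an equal p across these lists, and the shortest list is cut at the strictest p. At a −log10 p of at least 5 in all lists the ratios were 115.0 and 62.5.

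The next comparison asked how far the MCFDCIS replicates held the same regions. The shorter list lay almost wholly within the longer one. Of the replicate 2 peaks, 14455 of 15238 (94.9%, 94.5 to 95.2) overlapped a replicate 1 peak by at least 1 bp, against a mean of 0.545% when positions were shuffled within chromosomes and 1.13% when each peak was moved by 10 to 100 kb. Of the replicate 1 peaks, 14344 of 28239 (50.8%, 50.2 to 51.4) overlapped a replicate 2 peak, against 0.300% after shuffling. The strongest peaks of either list were found in the other. All 2824 replicate 1 peaks in the top 10% by −log10 q overlapped a replicate 2 peak, while 4.96% of those in the lowest 10% did. The 13895 peaks listed in replicate 1 and not in replicate 2 had a median fold of 5.30, against 13.6 for those found in both, and only 7 of the 4231 peaks of at least 20-fold were among them. The 783 peaks listed in replicate 2 and not in replicate 1 had a median fold of 4.67, against 8.11 for those in both. With the lists cut to equal length, the top 15238 peaks of replicate 1 were found in replicate 2 in 81.9% of cases and the reverse share was 82.7%.

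**Figure D1:**
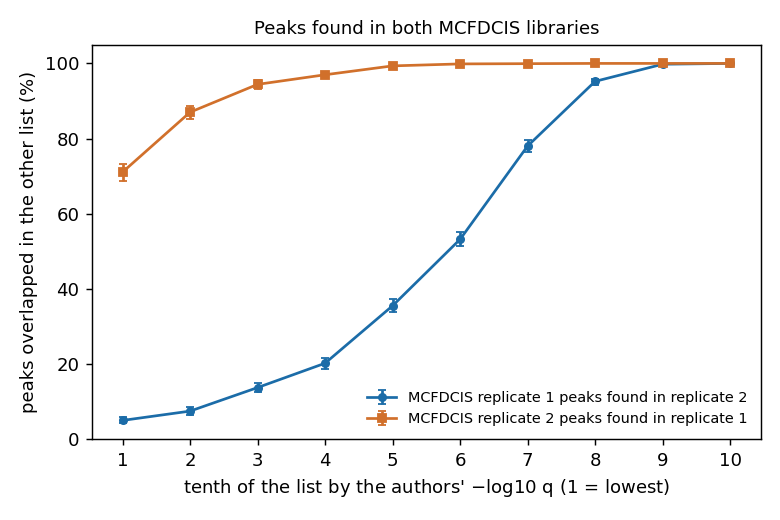
Share of peaks (%) of each MCFDCIS replicate that overlapped a peak of the other replicate, with the peaks of each list divided into 10 equal groups by the authors' −log10 q. Bars are 95% Wilson intervals; the share rises from 4.96% to 100% for replicate 1 and from 71.1% to 100% for replicate 2.

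Overlapping peaks merged into 14336 regions that were present in both replicates, with a median width of 341 bp. The strongest summits of a region lay a median of 14 bp apart, and 92.4% of the regions had summits within 50 bp. The order of the regions was shared. Spearman's rho across regions was 0.763 for the authors' fold (bootstrap interval 0.758 to 0.769) and 0.925 (0.922 to 0.928) for the summit fragments over the genome-wide background of the library, called relative height below. Regions are not independent replicates, so no p-value is attached to either. Relative height was greater in replicate 1 in 14116 regions (98.5%), with a median ratio to replicate 2 of 1.86 (1.85 to 1.87). With regions ranked by the lower of their 2 folds, the ratio was 1.85 in the lowest 10% and 1.74 in the highest 10%.

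**Figure D2:**
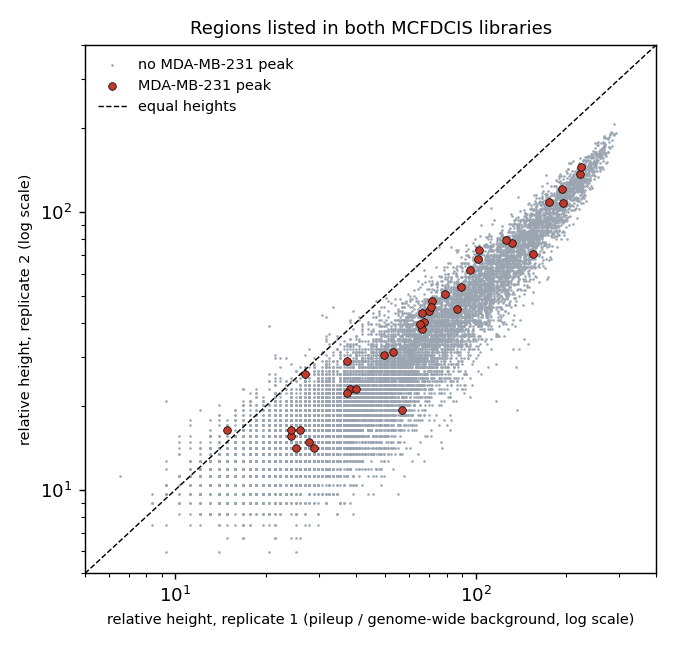
Relative height (fragments over the summit divided by the genome-wide background, log scales) of the 14336 regions listed in both MCFDCIS replicates, replicate 1 against replicate 2. Each point is 1 region, red points are the 36 regions with an MDA-MB-231 peak, and 98.5% of the regions lie on the replicate 1 side of the dashed line of equal heights.

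The 15 strongest shared regions, ranked by the lower of their 2 folds, lay on 10 chromosomes and had lower folds of 45.0 to 59.1 (positions in hg19). The first was on chromosome 20 from 36023209 to 36023697, with a fold of 60.6 ± 2.10 (SD, n = 2, as for the folds that follow) and 273 and 216 fragments over its summit in replicates 1 and 2. A region on chromosome 10 from 80679678 to 80680311 followed at 57.6 ± 3.73, with 265 and 195 fragments. The third, on chromosome 11 from 1851435 to 1852708, had a fold of 53.4 ± 0.41 and the fourth, on chromosome 14 from 87486475 to 87486916, had 51.9 ± 0.86. On chromosome 16 the region from 88576649 to 88577225 had a fold of 55.3 ± 6.70. On chromosome 20 there were further regions from 45530015 to 45530681, at 61.7 ± 15.9, and from 22743088 to 22743603, at 50.1 ± 7.18. A further region of chromosome 11, from 118858888 to 118859467, had a fold of 53.1 ± 6.24, and one of chromosome 22, from 43145419 to 43145941, had 54.0 ± 8.37. On chromosome 8 the region from 116283486 to 116283972 was listed at 75.0 in replicate 1 and 47.5 in replicate 2, the widest gap of the 15, and the region from 144980152 to 144980558 had 48.1 ± 4.06. On chromosome 6 the regions from 46789297 to 46789667 and from 36643830 to 36644572 had folds of 48.5 ± 3.20 and 45.6 ± 0.77. The remaining regions of the 15 were on chromosome 3 from 53303848 to 53304393, at 45.7 ± 0.34, and on chromosome 2 from 220151059 to 220151747, at 46.6 ± 1.65. The summit held more fragments in replicate 1 in 15 of 15, although replicate 2 was the deeper library, and the fold was higher in replicate 1 in 11 of 15. Their summits held up to 306 fragments in replicate 1, not far below a ceiling of 328, so the tallest can be compressed. None of the 15 had a called peak in MDA-MB-231.

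The last comparison asked which MCFDCIS regions were also called in MDA-MB-231. Of the 14336 shared MCFDCIS regions, 36 (0.251%, Wilson interval 0.181 to 0.347) overlapped an MDA-MB-231 peak and 14300 did not. By the lower of their 2 folds, those 36 were mostly weak in MCFDCIS, with 32 under 10, as were 8955 of all 14336 shared regions. The fold is taken over local background, and their summits were not all low. Relative height in replicate 1 ran from 14.9 to 222.6 in the 32, beside a median of 53.1 over all shared regions. Among regions with a lower fold of at least 10 there were 4 of 5381, among those of at least 20 there were 2 of 1466, and among those of at least 40 there were 0 of 58. At the depth of MDA-MB-231, most of the 14300 would have been detectable had they been as high as in either MCFDCIS replicate. How well the ChIP enriched in the single MDA-MB-231 library was not tested, so a missing call does not show an unbound region. The smallest MDA-MB-231 peak over the genome-wide background held 8 fragments. On the assumption that local background stood as far above the genome-wide level as in the replicate compared, the replicate 1 height was a median of 4.82 times the height needed for a call in MDA-MB-231, and at least 2 times that height in 13123 regions (91.8%). With replicate 2 the median was 2.56 times and 9238 regions (64.6%) reached 2 times. Without peaks on high local background, of at least 5 times the genome-wide level, 7 of 10406 shared regions had an MDA-MB-231 peak instead of 36 of 14336. A high background in any 1 of the lists was enough to remove a match.

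Read from the MDA-MB-231 side, 74 of its 244 peaks (30.3%, exact 95% interval 24.6 to 36.5) overlapped a replicate 1 peak, against 4.28% after shuffling. Of these 74, 12 lay on the mitochondrial sequence, and 62 of the 232 other peaks (26.7%) overlapped. The shuffle kept each peak on its own chromosome, and replicate 1 peaks covered 52.7% of the mitochondrial span. The 4.28% therefore includes mitochondrial overlaps and is not the level to set beside the 232. For replicate 2 the number was 35 (14.3%, 10.199 to 19.4) against 0.279%, and for the shared regions it was 34 (13.9%, 9.85 to 18.9) against 0.311%. The overlap sat at the top of the MDA-MB-231 list. All of its top 25 peaks by −log10 q were found in replicate 1 and 22 in replicate 2, whereas 49 of the other 219 (22.4%) were found in replicate 1 and 13 in replicate 2. The 169 peaks found in neither MCFDCIS list mostly had low summits, with a median of 13 fragments against 54 for the 75 found in either. Their median fold of 4.82 was close to the 5.00 of the whole list. Of the 46 MDA-MB-231 peaks with a −log10 q of at least 10, 7 were in neither list. When each MCFDCIS list was cut to its own top 244 peaks, 2 of the 244 MDA-MB-231 peaks (0.820%) were found in replicate 1 and 1 (0.410%) in replicate 2. The overlap with replicate 1 was 56.0% at a −log10 q of at least 5. It was 10.1% when peaks on high local background were left out of each list, which also removes partners.

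The 10 MDA-MB-231 peaks with the highest −log10 q were all listed in both MCFDCIS replicates, at folds of 7.56 to 23.1 in MDA-MB-231, 3.52 to 9.32 in replicate 1 and 2.26 to 5.52 in replicate 2. The folds come from separate lists, each against its own background, and are given side by side without a test. The first, on chromosome 21 from 9825340 to 9827674, had a −log10 q of 239.6 and 286 summit fragments (exact Poisson interval 254 to 321), with a fold of 17.3 in MDA-MB-231, 9.13 in replicate 1 and 5.23 in replicate 2. The second, on chromosome 1 from 91852685 to 91853248, had 311 fragments and a fold of 9.34. The highest fold, 23.1, was on chromosome 17 from 31149306 to 31149970. Folds of 21.8 and 12.7 were listed for neighbouring peaks on chromosome 20 from 26188715 to 26189489 and from 26189685 to 26190495. The others were on chromosome 17 from 33478019 to 33478398 (16.8), chromosome 16 from 33962925 to 33963513 (12.1), chromosome 1 from 156186175 to 156186715 (11.4), chromosome 5 from 71146626 to 71147055 (10.17) and chromosome 11 from 85194894 to 85195364 (7.56). Their local background was 2.63 to 24.4 times the genome-wide level in MDA-MB-231, 6.36 to 47.7 times in replicate 1 and 8.63 to 47.2 times in replicate 2, and it was higher in each MCFDCIS replicate than in MDA-MB-231 at 10 of 10. Relative height in MDA-MB-231 was 0.989 to 1.27 times that in replicate 1 and 1.48 to 2.21 times that in replicate 2. All of the 15 MDA-MB-231 peaks with a fold of at least 10 were found in replicate 1 and 13 in replicate 2.

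The 4 strong shared regions with an MDA-MB-231 peak are named here after their values were seen. On chromosome 19 from 47734355 to 47735299 the fold was 57.6 and 37.0 in replicates 1 and 2 and 5.53 in MDA-MB-231, where the summit held 27 fragments (17.8 to 39.3). On chromosome 12 from 2113550 to 2114081 the folds were 56.5, 31.8 and 5.79, also with 27 fragments in MDA-MB-231. On chromosome 17 from 55945250 to 55946049 they were 14.8, 13.7 and 6.40, with 51 fragments (38.0 to 67.1). On chromosome 3 from 48454469 to 48454821 they were 29.4, 10.8 and 5.10, with 11 fragments (5.49 to 19.7).

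**Figure D3:**
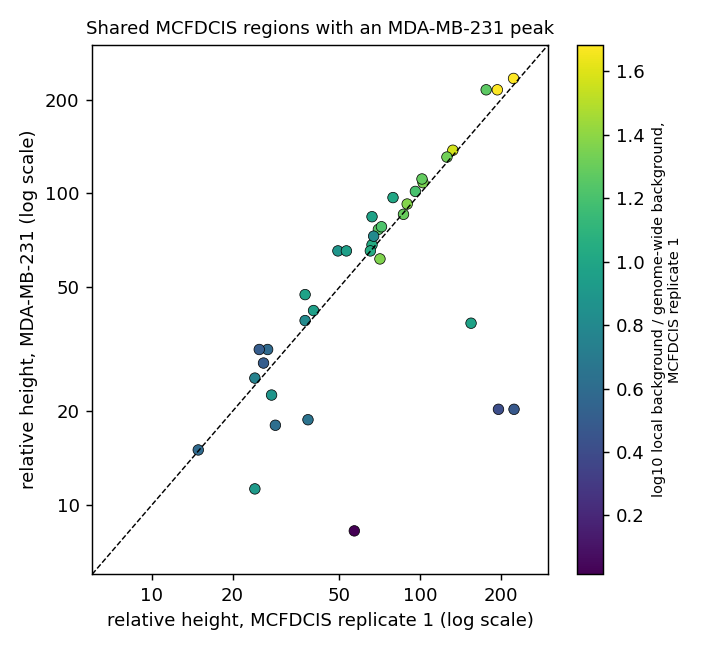
Relative height (fragments over the summit divided by the genome-wide background, log scales) of the 36 shared MCFDCIS regions with an MDA-MB-231 peak, MCFDCIS replicate 1 against MDA-MB-231, coloured by the log10 ratio of local to genome-wide background in replicate 1; the dashed line marks equal heights. The 4 regions with a lower fold of at least 10 in MCFDCIS lie below the line, and 26 of the other 32 lie above it.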

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

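All tests in this part were chosen after the peaks on the mitochondrial sequence were seen, and the prediction on summit distances was written before its result. Those peaks lie outside the nuclear regions that the comparisons describe. MCFDCIS replicate 1 listed 15 mitochondrial peaks and MDA-MB-231 listed 12, while replicate 2 listed 0; replicate 1 and MDA-MB-231 share a date. The 15 peaks covered 52.7% of the mitochondrial span with folds of 1.29 to 1.56 and a median of 315 summit fragments. The 12 peaks covered 37.8% with folds of 1.43 to 1.66. Elsewhere, folds under 2 were listed for 3 of 28224 peaks in replicate 1 and 4 of 232 in MDA-MB-231.

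A candidate explanation is more mitochondrial DNA in these ChIP libraries than in what they were called against. It was not possible to test this from the folds. The median mitochondrial background was 222 fragments in replicate 1 and 220.4 in MDA-MB-231, and with at most 2 fragments per bp of fragment length the fold at that median could reach no more than 1.475 and 1.5762, so low folds would follow from any cause. Binding at fixed mitochondrial sites would place the summits together; 7 of 12 summits (58.333%) lay within 100 bp of one in replicate 1, between the limits set for and against it. Rotating the summits together along the sequence gave a mean of 2.19 within that distance and as many as 7 in 0.0083 of 10000 draws, while placing them at random within their own peaks gave 4.43 and 0.0772, so the overlap of the peaks could account for part of this and fixed sites stay open. A difference between the cell lines does not account for peaks in 1 MCFDCIS replicate and not in the other; the shared date stays open and was not tested.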

How the results depend on the processing

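Chosen after the data were seen were the exclusion of high local background, the common p threshold, all values of relative height, the values on chromosomes 1 to 22 and X other than peak counts and their ratios, and the values of the 15 strongest regions with 1 replicate left out; the others were planned. Of 98 alternative values over 15 results, 62 stayed within the spread or 1.5 times the count, 36 moved and 0 changed direction. Most of the 15 results are counts or shares, which have no direction to change, so the last number says little. A common −log10 p of at least 5 and chromosomes 1 to 22 and X moved none of those recomputed. Of 30 values for the 15 strongest regions with 1 replicate left out, 15 moved, since the lower fold was then replaced by the other.

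At a −log10 q of at least 5, replicate 2 peaks in replicate 1 were 96.3%, the reverse share 54.2% and rho of the folds 0.750. MDA-MB-231 peaks numbered 91, with 56.0% in replicate 1 and 29.7% in replicate 2, and the peak ratios were 271.9 and 154.0. At 10 these were 97.7%, 57.1%, 0.711, 46 peaks, 60.9%, 39.1%, 395.5 and 232.2, with 18195 peaks in replicate 1, 19 shared regions with an MDA-MB-231 peak and a rho of relative height of 0.930. Shorter lists by construction lose the weak peaks. Without high local background the replicate shares were 77.0% and 45.2%, rho of height 0.899, shared regions with an MDA-MB-231 peak 7, and MDA-MB-231 shares 10.1% and 5.53%. That exclusion acted on each list alone and removed 5214 replicate 1, 1655 replicate 2 and 45 MDA-MB-231 peaks. Peaks whose partner was removed count as unmatched by construction, and how much of the fall this makes up was not measured. Reciprocal overlap of 50% gave 88.7%, 47.8% and a rho of height of 0.929. Summits within 100 bp gave 93.2%. Equal list lengths gave 82.7%, 81.9%, a rho of folds of 0.742, a height ratio of 1.91 and MDA-MB-231 shares of 0.820% and 0.410%. With 1 MCFDCIS replicate left out, MDA-MB-231 peaks in MCFDCIS ranged from 14.3% to 30.3%, against 13.9% with both; the higher value is without replicate 2. Where no construction is named, the cause was not tested.

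Not run, for want of an hg19 genome and annotation here, were the p53/p63 site share, other motif shares, peaks by genomic feature and gene lists, with all their alternatives. No paired analysis was possible because no result comes from a test between groups. The lowest listed summits held 6, 7 and 8 fragments in replicate 1, replicate 2 and MDA-MB-231, so binding below these levels is not seen here. They followed the p thresholds of the lists, not the order of their depths.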

Other observations

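The tests of depth, of background and of carry-over were chosen after the values they rest on were seen; the predictions of the others were written before their results. Shared MCFDCIS regions lay close together more often than shuffled ones. Of 14335 regions on chromosomes 1 to 22 and X, 3404 (23.7%) lay within 10 kb of another, against 9.38% after shuffling within chromosomes (highest of 100 draws 10.18%). Unmappable sequence left out of the shuffle would let regions moved by 10 to 100 kb come as close; they reached 16.8%, which is 70.608% of the observed share. Chains of at least 4 regions, each within 10 kb of the next, numbered 76, against a mean of 1.72 and a highest value of 5 after shuffling. Chains were set beside the shuffle within chromosomes alone. Moves of 10 to 100 kb brought more regions close together than that shuffle did, so the excess of chains may be overstated. The longest had 9 regions over 29.1 kb of chromosome 3, from 52072267 to 52101387, with a highest lower fold of 44.5. Chains of 7 lay on chromosome 19 from 18467368 to 18497187 and on chromosome 10 from 74074726 to 74095082. Regions in company were little taller than isolated ones, with a ratio of median relative heights of 1.125, under the 1.2 set for a link between clustering and strength. Among chromosomes 1 to 22, shared regions ranged from 2.89 per Mb on chromosome 13 to 7.42 per Mb on chromosome 17, and chromosome X held 2.59 per Mb. The spans were not corrected for unmappable sequence, which lowers the density of chromosomes that hold much of it.

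The MDA-MB-231 peaks at shared MCFDCIS regions fell into 32 weak and 4 strong regions, below and above a lower fold of 10 in MCFDCIS. Carry-over of MCFDCIS chromatin or reads would leave lower heights in MDA-MB-231 and favour the tallest regions. Relative height above local background was lower than in replicate 1 in 12.5% of the weak regions, with a median ratio of 1.18. Only regions called in MDA-MB-231 enter that share, which can leave low heights out. The 4 strong regions went the other way, with ratios of 0.0781 to 0.227, as carry-over would leave. Yet of the tallest 10% of all strong regions 1 of 538 (0.186%, Wilson interval up to 1.05%) had a peak. At the weak regions the median local background was 9.86 and 10.6 times the genome-wide level in replicates 1 and 2. It was 3.18 and 2.66 at the 8923 other weak regions, and 5.11 in MDA-MB-231 itself at the same regions. None of 10000 random sets of the other weak regions was as high in both (0.0001, the smallest share these draws can give). The sets were not matched on height, and a tall region has a fold under 10 only on a high background. The difference can therefore follow in part from the fold line. Collapsed or multicopy sequence is a candidate explanation there, which this comparison does not settle. At the strong regions on chromosomes 19, 12 and 3 it was 2.96 and 3.19, 2.55 and 2.66, and 1.03 and 1.12 times that level, and at least 40.301% of the other strong regions were as high in either library, which argues against high background; on chromosome 17 it was 9.55 and 4.46, as high in 1.06% of the others in replicate 1 and 16.6% in replicate 2, and there it stays open. Binding of p63 or a related protein in both lines stays open and was not tested.

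Replicate 1 of MCFDCIS listed 1.85 times as many peaks as replicate 2. Depth went the other way, since replicate 1 had 0.7806 of the depth of replicate 2. Different sites are not seen at the top, since 3 of the 2854 tallest replicate 1 peaks (0.1051%) were absent from replicate 2. A single lower enrichment in replicate 2 was taken as the 1.83-fold height ratio of the tallest peaks. It would have left 22940 of the replicate 1 peaks above the replicate 2 threshold, 1.5993 times the 14344 found. On its face this excess goes against a single lower enrichment as the whole cause. The prediction starts from peaks chosen for passing in replicate 1, which can raise it, and by how much was not measured. The test therefore does not settle whether enrichment was lower in replicate 2. Other differences between the dates stay open and were not tested.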
